A study of Mus musculus with 8 samples.

How the data were processed

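The study measured polyadenylated RNA in primary hepatic stellate cells from male wild-type C57BL/6 mice. The cells had been transfected with a control siRNA or with an siRNA against PAK4, with 4 libraries in each group. Per the labels' protocols, each library was prepared separately from 1 µg of total RNA with a stranded mRNA kit, and all 8 samples carry the same label for batch 1. The labels number the replicates of each group from 1 to 4 and do not say whether they came from separate animals, isolations or dishes, so the p-values measure the spread between these samples, which may be technical.

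A single table deposited by the authors held whole-number read counts, FPKM and TPM for 45777 genes, with NCBI gene identifiers and symbols, per the file headers. The read counts were used as the authors deposited them, with no normalization. The FPKM values deposited by the authors are scaled to sequencing depth and gene length, and the deposited TPM values are scaled further to a fixed total per library; these served only in alternative fits. Per the submitters' processing notes, bcl2fastq 2.20.0, FastQC 0.11.7, HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 2.1.3b were used, with genome build mm10. The step that produced the counts, its strand setting and its handling of reads that match several genes are not given in the sources used here. Near-identical genes such as Ifit3 and Ifit3b, Gsta1 and Gsta2, Serpina1a and Serpina1c or Oas1a and Oas1b may therefore share reads, and their separate values are uncertain. So are those of Rn18s-rs5, a sequence related to the 18S ribosomal RNA repeat. Every value column was matched to its sample by the library name in the labels, and 0 columns were left over. No pair of libraries within a group agreed within sampling noise, with a chi-square per degree of freedom of 12.7 to 67.8 over genes, so each was counted as 1 sample.

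Counts summed to between 55728583 and 61535063 per library. In total 17287 genes had no read in any library. Genes were kept for testing by the filterByExpr function of edgeR 4.0.16 (minimum count 10), which left 17975. Libraries were scaled by TMM, and siPAK4 was compared with siControl by edgeR's quasi-likelihood test with robust estimation, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Adjusted p-values of genes are from that test throughout. CPM values were computed by edgeR on the TMM-scaled library size. Fold changes are siPAK4 over siControl, and standard errors of log2 fold changes were derived from the quasi-likelihood F statistic.

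A total of 23 gene lists and 8 lists of cell type markers were written before the data were examined. They covered stellate cell activation, stellate cell quiescence, collagens, matrix proteases and inhibitors, TGF-beta response, YAP and TAZ targets, SRF and MRTF actin cytoskeleton genes, focal adhesion, mitosis, DNA replication, Wnt targets, NRF2 targets, fatty acid oxidation, type I interferon response, inflammatory chemokines and cytokines, p53 targets, the unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, CREB and immediate early genes, and lysosome and autophagy, besides 1 list whose result is not reported here. The markers were those of hepatocytes, macrophages, endothelial cells, cholangiocytes, lymphocytes, neutrophils, portal fibroblasts with mesothelial cells, and vascular smooth muscle. Each list with at least 3 tested members was tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 31 lists. Camera was repeated with the correlation estimated from the data, and fry served as a test of each list by itself. Some genes belong to several lists: 20 of the 30 activation genes are also in another list. Members written with another symbol were matched through a RefSeq table of assembly GRCm38.p6, the build also called mm10. That table matched 45679 of the gene identifiers and gave the coordinates, which are counted from 1.

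The genes named were chosen by a rule also fixed before the data were examined. It took the PAK kinases, 11 stellate cell genes whatever their test, and the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap. It also took the 5 smallest p-values in each direction, and up to 4 members of each list with the smallest adjusted p (2 by expression where none passed). Genes outside this rule are said to have been chosen after their values were seen.

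The procedure was tested on simulated counts for siPAK4 against siControl with 4 libraries each and the 17975 tested genes. It called 58.2% of genes changed by 1.5-fold, 68.7% of those changed by 2-fold and 98.5% of those changed by 4-fold, with 7.41% of the calls on unchanged genes. Camera called 3 of 3 shifted lists and 0 of 27 lists with no shifted member. The simulated genes varied independently, so the list counts do not show how often camera errs where genes are correlated. Far fewer genes were changed in the simulation than the 26.9% called in the data, so its rates may not carry over.

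The alternatives were other scalings (RLE, library totals), DESeq2 1.42.0, limma-voom, no filter or a minimum mean of 1 CPM, a stricter threshold of 0.01, non-robust estimation, the replicate number as a block, limma-trend on log2 of TPM or FPKM with a pseudocount of 1 or 0.1, camera on ranks, and each library left out in turn. A correction for GC content and transcript length, with values from the longest GENCODE transcript of each gene, was added after the data were seen. R 4.3.3 was used.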

Results

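Hepatic stellate cells are the vitamin A-storing cells of the liver sinusoid that turn into collagen-producing myofibroblasts in culture or after injury. PAK4 is a p21-activated kinase that acts downstream of CDC42 on the actin cytoskeleton. RNA was sequenced from primary mouse stellate cells transfected with a control siRNA or an siRNA against PAK4 as they activated, and the comparison asked how the transcriptome differs when PAK4 is low. There were 4 siControl and 4 siPAK4 libraries, with 57297561 to 61535063 counts per siControl library and 55728583 to 59205049 per siPAK4 library. The group separation was the largest source of variation: the first principal component held 44.1% of the variance and parted the groups. The second component, with 13.4%, set siPAK4 replicate 3 apart from the other siPAK4 libraries.

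Pak4 (NCBI gene 70584, mm10 chromosome 7, 28558819 to 28598184) was lower in every siPAK4 library than in any siControl library. Its level was 17.2 ± 1.14 CPM in siControl and 6.32 ± 1.13 CPM in siPAK4 (SD, n = 4 each), a log2 fold change of −1.44 (SE 0.118, adjusted p = 9.4e-06). The counts were 1028, 993, 964 and 915 in siControl replicates 1 to 4 and 447, 335, 311 and 393 in siPAK4 replicates 1 to 4. Among the other family members Pak1 fell by a smaller amount (log2 fold change −0.47, adjusted p = 0.0061). Pak2 (−0.13, adjusted p = 0.14), Pak3 (−0.22, adjusted p = 0.25) and the weakly expressed Pak6 (0.80, adjusted p = 0.15) did not pass the test. Pak5, listed as Pak7, had 3 reads in a single library and was not tested.

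The siPAK4 libraries differed from the siControl libraries in 4832 of 17975 tested genes, of which 2227 were higher and 2605 lower (46.1% higher). At least 2-fold changes were found for 831 genes, 363 higher and 468 lower. The 2 groups did not overlap in 28.8% of tested genes, where chance gives 2.86%. The balance of directions depended on the scaling: with library totals alone, 3877 genes were higher and 1859 lower (67.6% higher), and with FPKM and a pseudocount of 1, 3601 were higher and 1715 lower (67.7% higher). At least 2-fold, FPKM with that pseudocount gave 137 higher and 83 lower genes (62.3% higher, against 43.7% by TMM).

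**Figure D1:**
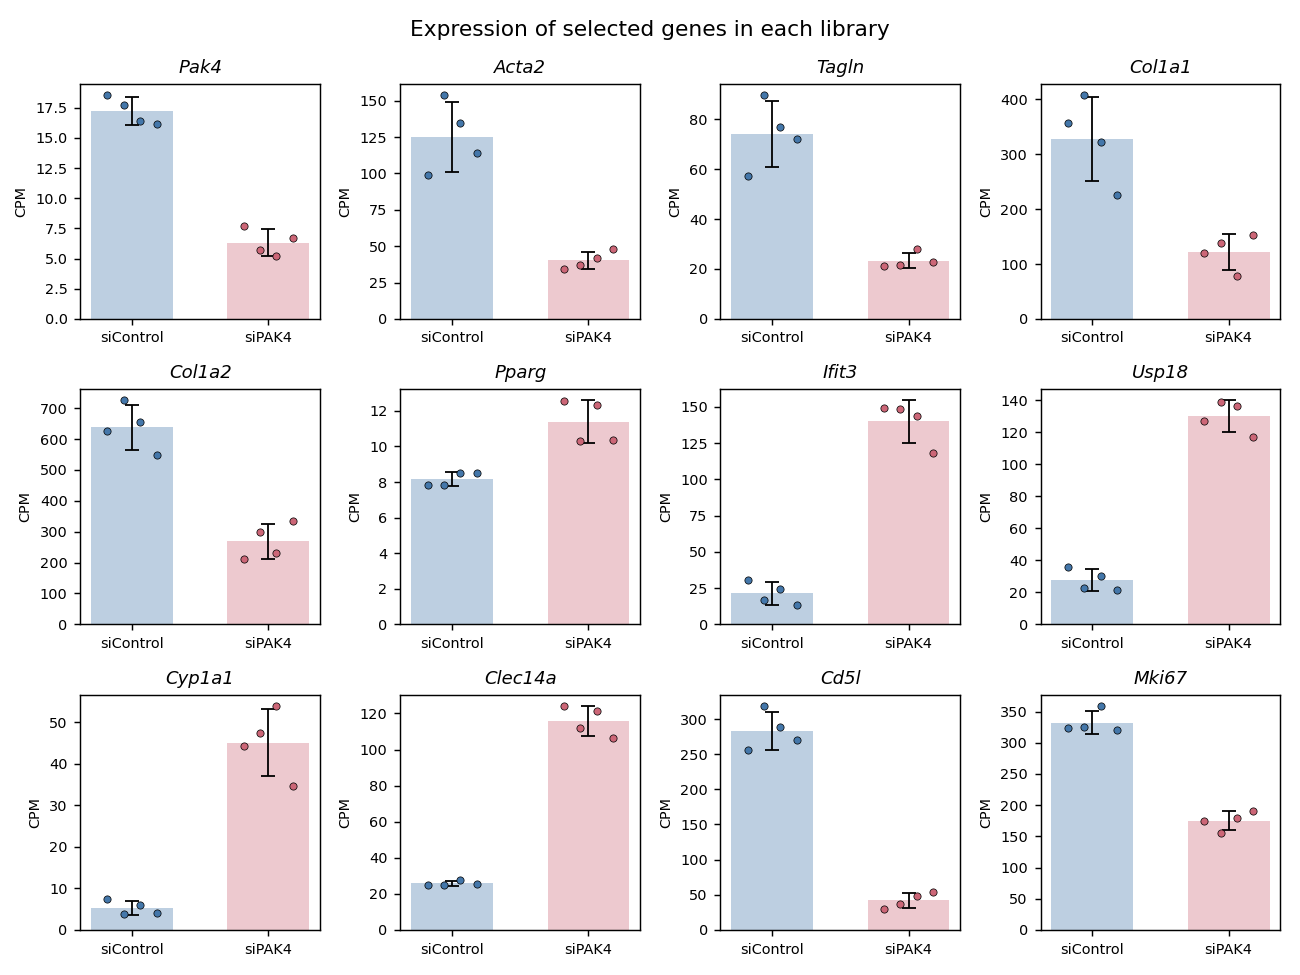
CPM of 12 genes in each library, with a panel per gene; bars are group means, error bars are SD (n = 4) and points are libraries. Pak4, Acta2, Tagln, Col1a1, Col1a2, Cd5l and Mki67 were lower and Pparg, Ifit3, Usp18, Cyp1a1 and Clec14a higher in all siPAK4 libraries than in any siControl library; Pak4 averaged 17.2 CPM in siControl and 6.32 CPM in siPAK4.

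Genes known from activated, myofibroblast-like stellate cells fell with siPAK4, in libraries that do not show which cells each transcript came from. Acta2, the smooth muscle actin used as the standard mark of activation (chromosome 19, 34240336 to 34255585), went from 125 ± 24.1 to 40.4 ± 5.94 CPM, a log2 fold change of −1.63 (SE 0.138, adjusted p = 1.3e-05). Tagln, which encodes the actin-binding protein SM22, fell from 74.1 ± 13.4 to 23.4 ± 3.06 CPM (log2 fold change −1.67, adjusted p = 8.2e-06). The matrix glycoprotein genes Tnc (−1.89) and Thbs1 (−1.30), the growth factor receptor gene Pdgfrb (−0.85), Ccn2 (−0.70) and the protease inhibitor gene Timp1 (−0.60) also fell, with adjusted p of 0.0014 or below. Tgfb1 did not pass (−0.18, adjusted p = 0.44). Of 29 tested activation genes, 25 were lower, 0 higher and 4 did not pass, and 25 were lower when adjusted over the list alone; camera called the list (median log2 fold change −0.79, adjusted p = 1.8e-27). In the same libraries the portal fibroblast and mesothelial markers had a median of −0.64 and the vascular smooth muscle markers, 3 of which are also in the activation list, a median of −0.46.

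The collagen list moved the same way, with 28 of 31 genes lower, 0 higher and 3 not past the test (28 lower when adjusted over the list alone; median −0.80, camera adjusted p = 7.8e-30). Col1a1, which encodes a chain of the main fibrillar collagen (chromosome 11, 94936224 to 94953042), went from 328 ± 77.1 to 122 ± 32.7 CPM (log2 fold change −1.42, SE 0.224, adjusted p = 0.0014), and Col1a2 from 639 ± 72.9 to 268 ± 56.8 CPM (−1.25, SE 0.137, adjusted p = 6.9e-05). Col3a1 (−1.10), Col5a2 (−1.09), Col4a5 (−1.14) and Col14a1 (−2.07) fell with adjusted p of 9.8e-06 or below. The matrix proteases and inhibitors went both ways, with 8 higher, 9 lower and 10 not past the test (8 and 10 when adjusted over the list alone), and camera did not call the list (median −0.08, adjusted p = 0.30). In it the inhibitor genes Timp2 (−0.79) and Timp3 (−0.97) and the protease gene Adamts12 (−1.07) fell while Adamts1 (0.97) rose, all with adjusted p of 4.3e-05 or below.

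Genes typical of quiescent stellate cells went both ways. Of 23 tested, 7 were higher, 4 lower and 12 did not pass, with the same counts when adjusted over the list alone. The median was 0.17, the mean −0.0025, and the camera test pointed up without passing (adjusted p = 0.53). By fry, which tests the list by itself, it was called higher (adjusted p = 0.016). Pparg, a lipid-handling transcription factor of the quiescent state, rose from 8.18 ± 0.378 to 11.4 ± 1.21 CPM (log2 fold change 0.48, adjusted p = 0.0029) and Angptl6 rose (0.94, adjusted p = 0.0009), while Ecm1 fell (−0.91, adjusted p = 3.1e-05). Lrat, which encodes the enzyme that esterifies retinol for storage, had too few reads to test: 2, 4, 0 and 0 counts in siControl replicates 1 to 4 and 11, 11, 22 and 7 in siPAK4 replicates 1 to 4.

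Actin cytoskeleton genes known as targets of SRF and its MRTF cofactors fell: 23 of 28 were lower, 0 higher and 5 did not pass (24 lower when adjusted over the list alone; median −0.52, camera adjusted p = 1.4e-18). Besides Acta2 and Tagln, Myl9 (−1.29, adjusted p = 3.1e-05) and Cald1 (−0.75, adjusted p = 3.5e-05), which act in smooth muscle contraction, were among them. The vascular smooth muscle markers, which share 3 genes with this list, had a median of −0.46. Of 24 YAP and TAZ targets, 11 were lower, 1 higher and 12 did not pass (12 and 1 when adjusted over the list alone), with falls of Tgfb2 (−1.91), Fgf2 (−0.91), Ccn1 (−0.90) and Dock5 (−0.85). Camera called that list lower (median −0.33, adjusted p = 6.2e-08), but not in the repeat (adjusted p = 0.20 with an estimated correlation). Of 28 focal adhesion and integrin genes 16 were lower, 2 higher and 10 did not pass (19 and 3 when adjusted over the list alone), among them Cav1 (−0.80), Vcl (−0.55), Itgb1 (−0.51) and Tln1 (−0.49), which fell. The camera adjusted p was 8.6e-07 (median −0.36; adjusted p = 0.26 with an estimated correlation).

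Among 22 TGF-beta response genes, 8 were lower, 5 higher and 9 did not pass (9 and 5 when adjusted over the list alone). Nox4, which encodes an NADPH oxidase, fell from 210 ± 11.4 to 72.2 ± 14.8 CPM (log2 fold change −1.54, adjusted p = 1e-05), and Ltbp2 (−0.96) also fell. The camera call was narrow (median −0.18, adjusted p = 0.033) and was lost in the repeat (adjusted p = 0.46 with an estimated correlation). It was also lost without siControl replicate 1 (adjusted p = 0.060), with library totals, limma-voom, TPM, FPKM, ranks, the GC and length correction and a minimum mean of 1 CPM, with adjusted p from 0.011 to 0.46 over all alternatives. Of 17 Wnt targets, 7 were lower, 1 higher and 9 did not pass (7 and 2 when adjusted over the list alone), with falls of Ccn4 (−1.61), Ccnd1 (−0.87), Dkk3 (−0.93) and Dkk2 (−1.31). Camera gave an adjusted p of 0.0021 (median −0.16; adjusted p = 0.22 with an estimated correlation and 0.079 on ranks).

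Cell cycle genes were lower with siPAK4. All 28 mitosis genes fell, also when adjusted over the list alone (28 lower; median −0.52, camera adjusted p = 1.6e-14; adjusted p = 0.23 with an estimated correlation). Mki67, the proliferation antigen, went from 332 ± 18.1 to 175 ± 14.8 CPM (log2 fold change −0.92, SE 0.0694, adjusted p = 6e-06), and Top2a (−0.64), Cenpe (−0.75) and Cenpf (−0.72) fell too. Of 30 DNA replication genes, 19 were lower, 0 higher and 11 did not pass (22 lower when adjusted over the list alone), among them the ribonucleotide reductase genes Rrm1 (−0.69) and Rrm2 (−0.68). Camera called this list lower (median −0.28, adjusted p = 3e-08; adjusted p = 0.32 with an estimated correlation). The p53 targets went both ways, with 3 higher, 8 lower and 14 not past the test (the same when adjusted over the list alone; median −0.13, camera adjusted p = 0.24, but called lower by fry with an adjusted p of 0.029); Plk2 (0.50) and Fas (0.70) rose and Sesn1 (−0.81) and Pmaip1 (−0.60) fell.

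Interferon-stimulated genes rose with siPAK4. All 39 tested members were higher, also when adjusted over the list alone (39 higher; median log2 fold change 1.47, camera adjusted p = 1e-75). Ifit3, an antiviral effector gene whose separation from the near-identical Ifit3b is uncertain, went from 21.3 ± 7.83 to 140 ± 14.6 CPM (log2 fold change 2.72, SE 0.232, adjusted p = 3.6e-05). Usp18, a negative regulator of the interferon receptor, rose from 27.5 ± 6.83 to 130 ± 9.96 CPM (2.24, adjusted p = 3.1e-06). The guanylate-binding protein gene Gbp2 (1.14), the RNA-sensor gene Dhx58 (1.47) and Oasl1 (1.85) rose with adjusted p of 3.9e-06 or below. In the same libraries the macrophage markers had a median log2 fold change of −0.66 and the hepatocyte markers a median of 1.97.

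Inflammatory genes rose as well: 24 of 33 chemokine and cytokine genes were higher, 2 lower and 7 did not pass (24 and 2 when adjusted over the list alone). Csf3, which encodes the granulocyte growth factor, rose from 3.34 ± 1.23 to 30.6 ± 10.9 CPM (log2 fold change 3.19, SE 0.326, adjusted p = 0.00011), Lcn2 by 2.77 and Il1b by 2.53 on the log2 scale. The acute phase gene Saa3 (1.44) and the NF-kB inhibitor gene Nfkbia (0.92) rose, while the chemokine gene Cxcl12 (−1.10) and the adhesion molecule gene Vcam1 (−0.56) fell. Camera called the list higher (median 0.54, adjusted p = 3e-18; adjusted p = 0.089 with an estimated correlation).

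**Figure D2:**
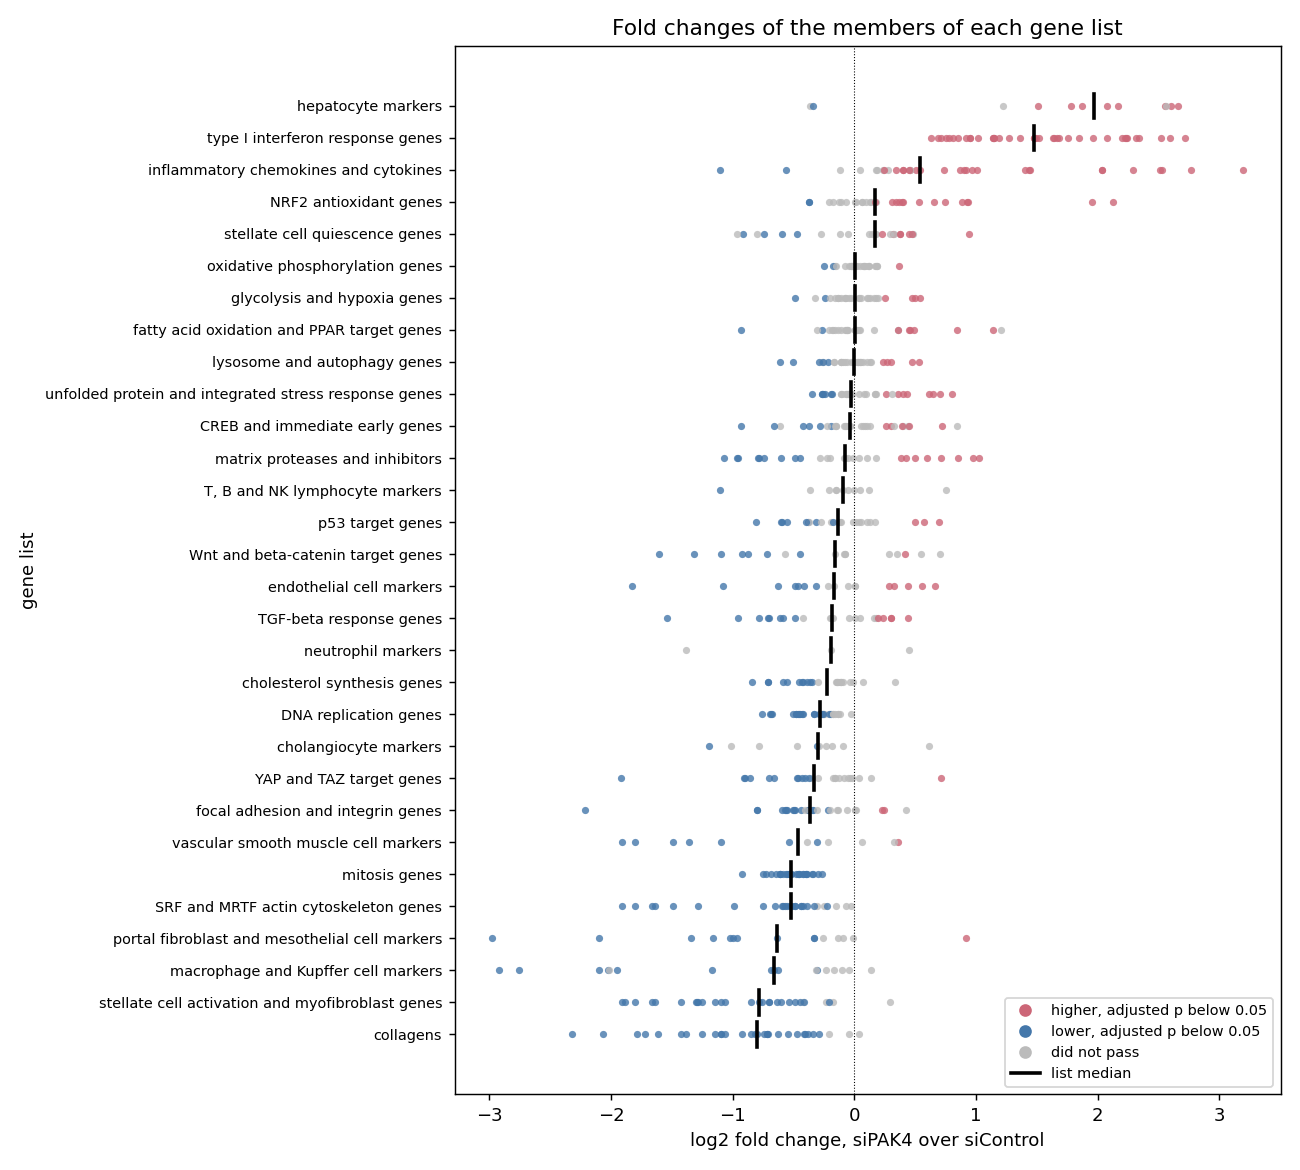
Log2 fold change of siPAK4 over siControl (horizontal axis) for each tested member of 30 gene and marker lists (vertical axis, ordered by median). Points are genes, coloured where the adjusted p is below 0.05, and black bars are list medians, which run from −0.80 for collagens to 1.97 for hepatocyte markers.

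Among stress and metabolic lists, the NRF2 antioxidant genes leaned higher, with 14 higher, 2 lower and 14 not past the test (15 and 3 when adjusted over the list alone). Gclc, which encodes the rate-limiting enzyme of glutathione synthesis (0.74), Gstp1 (0.65), Sqstm1 (0.53) and the weakly expressed Gsta1 (2.12, with an uncertain separation from Gsta2) rose. Camera gave an adjusted p of 1.5e-05 (median 0.17; adjusted p = 0.33 with an estimated correlation). Of 24 cholesterol synthesis genes 11 were lower, 0 higher and 13 did not pass (11 lower and 1 higher when adjusted over the list alone). Dhcr7 was among those that fell (−0.71). Camera called the list lower (median −0.23, adjusted p = 1.5e-05; adjusted p = 0.36 with an estimated correlation). In the unfolded protein and integrated stress response list 8 genes were higher, 7 lower and 17 did not pass (9 and 7 when adjusted over the list alone). The stress-response genes Atf4 (0.44), Ddit3 (0.80), Trib3 (0.70) and Ppp1r15a (0.62) rose. The list's median was −0.028, its mean 0.09 and the camera test pointed up without passing (adjusted p = 0.13, but 0.038 with library totals).

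The remaining metabolic and signalling lists were not called by camera. Fatty acid oxidation had 6 higher, 2 lower and 22 genes not past the test (6 and 2 when adjusted over the list alone; median 0.0023, adjusted p = 0.54), with a rise of Fabp4 (0.84) and a fall of Ucp2 (−0.93). Glycolysis and hypoxia had 4 higher, 2 lower and 20 not past it (4 and 2 when adjusted over the list alone; median 0.0029, adjusted p = 0.54), with rises of Slc2a1 (0.50) and Bnip3 (0.54). Oxidative phosphorylation had 1 higher, 2 lower and 26 not past it (1 higher and 0 lower when adjusted over the list alone; median 0.0055, adjusted p = 0.55), and the gene that rose was Ndufs3 (0.37, adjusted p = 0.00055). CREB and immediate early genes had 5 higher, 6 lower and 20 not past it (6 and 6 when adjusted over the list alone), with a median of −0.040, a mean of 0.0022 and an adjusted p of 0.97 for a test that pointed down; Ier3 rose (0.72) and Etv5 fell (−0.93). Lysosome and autophagy genes had 5 higher, 5 lower and 22 not past it (the same when adjusted over the list alone). Their median was −0.0061 and their mean −0.019, with a test that pointed up (adjusted p = 0.97); the cathepsin gene Ctsb fell (−0.51) and Gla rose (0.48).

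Transcripts of macrophages and endothelial cells were abundant in both groups, and several marker lists of other liver cell types differed between the groups. In siControl the endothelial gene Emcn averaged 653 CPM. The activation genes Pdgfrb, Acta2, Col1a2 and Thbs1 averaged 27.5, 125, 639 and 6568 CPM there. The labels do not describe the purity of the stellate cell preparation, so a change cannot be assigned to 1 cell type. Of 17 macrophage and Kupffer cell markers, 10 were lower, 0 higher and 7 did not pass (12 lower when adjusted over the list alone). Cd5l, which encodes a secreted macrophage scavenger protein, fell from 283 ± 27.3 to 42.0 ± 10.8 CPM (log2 fold change −2.75, SE 0.163, adjusted p = 2.3e-06), the complement gene C1qb from 199 ± 45.7 to 49.0 ± 11.4 CPM (−2.02, adjusted p = 8.1e-05) and the scavenger receptor gene Marco from 335 ± 39.3 to 148 ± 24.4 CPM (−1.17, adjusted p = 3.6e-05). Chosen after their values were seen, Adgre1 (386 CPM in siControl, log2 fold change 0.14, adjusted p = 0.34) and Cd68 (241 CPM in siControl, −0.04, adjusted p = 0.72), 2 general macrophage markers, did not pass. Camera called the macrophage list lower (median −0.66, adjusted p = 7.1e-13; adjusted p = 0.18 with an estimated correlation).

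Endothelial markers went both ways, with 5 higher, 7 lower and 5 not past the test (5 and 7 when adjusted over the list alone; median −0.17, camera adjusted p = 0.079). Emcn, an endothelial sialomucin gene, fell from 653 ± 17.8 to 308 ± 19.9 CPM (log2 fold change −1.08, adjusted p = 1.2e-06), Dnase1l3 (−1.83) and the sinusoidal scavenger receptor gene Stab1 (−0.41) fell, and Oit3 (0.44) rose. Without siPAK4 replicate 1 or siPAK4 replicate 4 the endothelial list was called lower (adjusted p = 0.015 and adjusted p = 0.019; 0.015 to 0.73 over all alternatives). Of 15 portal fibroblast and mesothelial markers 10 were lower, 1 higher and 4 did not pass (10 and 1 when adjusted over the list alone), including the mesothelial genes Upk3b (−2.10), Upk1b (−1.16) and Wt1 (−0.96) and the matrix gene Fbln2 (−1.34). Camera called this list lower (median −0.64, adjusted p = 1.4e-08; adjusted p = 0.14 with an estimated correlation). Of 12 vascular smooth muscle markers, 5 of which are also in another list, 7 were lower, 1 higher and 4 did not pass (9 and 1 when adjusted over the list alone), with falls of Cnn1 (−1.91) and Myh11 (−1.10). The camera adjusted p was 0.0029 (median −0.46; adjusted p = 0.14 with an estimated correlation).

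Hepatocyte markers were scarce and higher with siPAK4: 8 of 12 were higher, 1 lower and 3 did not pass (9 and 1 when adjusted over the list alone). Alb went from 1.75 ± 0.563 to 7.83 ± 2.96 CPM (log2 fold change 2.17, adjusted p = 0.00031) and Hp, an acute phase gene, from 14.3 ± 2.59 to 40.6 ± 10.2 CPM (1.51, adjusted p = 0.00016). Camera called the list higher (median 1.97, adjusted p = 6e-05; adjusted p = 0.23 with an estimated correlation), but not among genes with a mean of at least 1 CPM (adjusted p = 0.069). Cholangiocyte markers had 2 lower, 0 higher and 8 not past the test (2 lower when adjusted over the list alone; median −0.30, camera adjusted p = 0.13), with a fall of Tspan8 (−1.19); the list was called lower without siPAK4 replicate 3 (adjusted p = 0.042), with TPM or FPKM, on ranks, with no filter and by fry (adjusted p = 0.031), with adjusted p from 0.024 to 0.49 over all alternatives. Lymphocyte markers had 1 lower, 0 higher and 10 not past it (1 lower when adjusted over the list alone; median −0.09, camera adjusted p = 0.57), the gene that fell being Cd4 (−1.11). None of the 3 tested neutrophil markers passed, over all genes or when adjusted over the list alone (0 higher, 0 lower; median −0.19, camera adjusted p = 0.79), with S100a8 at 0.45 (adjusted p = 0.065, but 0.017 without siControl replicate 1) and Csf3r at −0.19 (adjusted p = 0.18).

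**Figure D3:**
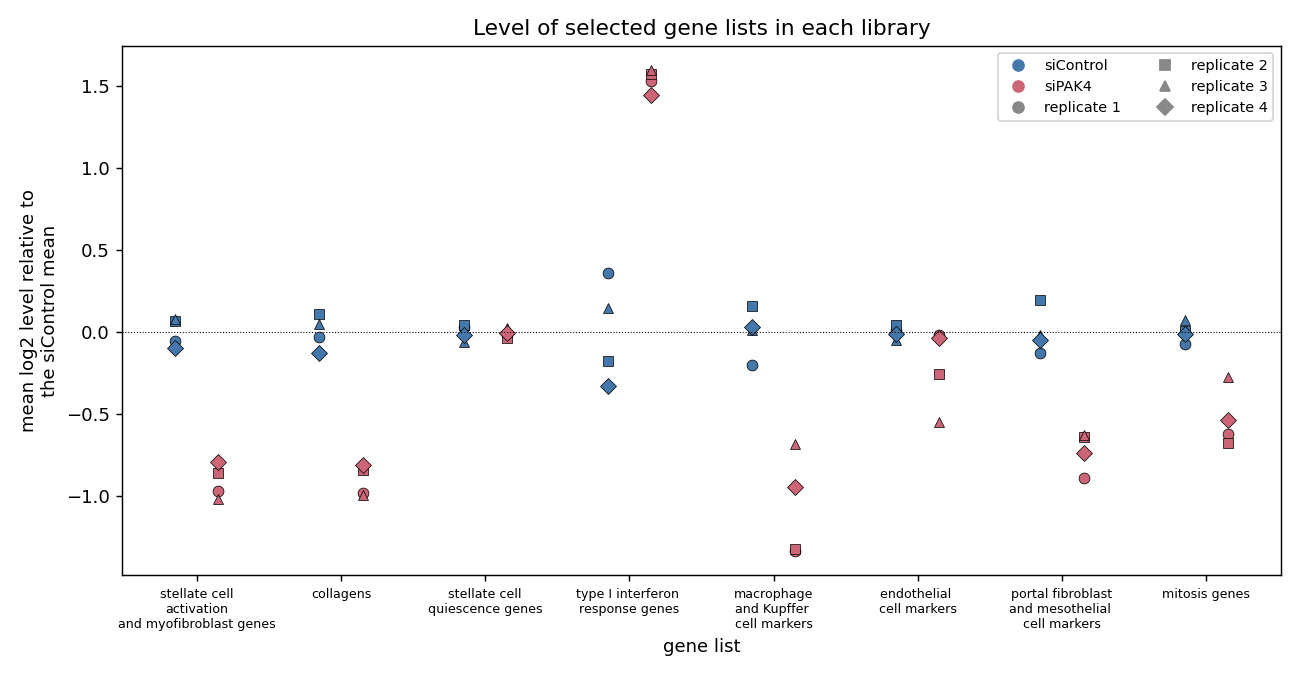
Mean log2 level of 8 gene and marker lists (horizontal axis) in each library, relative to the siControl mean (vertical axis); colours are groups and symbols are replicates. The interferon list lay between 1.45 and 1.60 in the siPAK4 libraries and between −0.33 and 0.36 in the siControl libraries, and siPAK4 replicate 3 had the highest macrophage level (−0.68) and the lowest endothelial level (−0.55) of the siPAK4 group.

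Across the 31 lists, camera called 17, of which 4 were higher and 13 lower, and fry called 21, of which 5 were higher and 16 lower. With an estimated correlation 4 held: stellate cell activation, collagens, SRF and MRTF targets, and the interferon response (adjusted p = 0.030, 0.046, 0.030 and 0.046).

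Rises and falls were ranked among genes past the threshold with a mean of at least 5 CPM and groups that did not overlap. Within these limits the largest rises outside the immune genes were those of Cyp1a1 and Aldh3a1. Cyp1a1, a xenobiotic-metabolizing cytochrome P450 gene, went from 5.32 ± 1.67 to 45.1 ± 8.01 CPM (log2 fold change 3.08, SE 0.205, adjusted p = 4.9e-06). Aldh3a1, an aldehyde dehydrogenase gene, went from 1.15 ± 0.309 to 9.15 ± 3.38 CPM (2.99, SE 0.275, adjusted p = 2.2e-05). The gene with the smallest p was Clec14a, which encodes an endothelial C-type lectin (chromosome 12, 58264720 to 58269258), at 25.8 ± 1.35 CPM in siControl and 116 ± 8.25 CPM in siPAK4 (2.17, SE 0.067, adjusted p = 1.4e-08). The antigen transporter gene Tap1 (0.97), the uridine phosphorylase gene Upp1 (1.45), Gbp4 (1.79) and Serpina3g (1.69) followed among the higher genes. Within the same limits the largest fall was that of Rn18s-rs5, an uncertain value because of its likeness to the ribosomal RNA repeat (−3.03, with 173 ± 93.4 CPM in siControl and 21.2 ± 4.44 CPM in siPAK4). Next came the tight junction gene Cldn1 (−2.98, from 22.5 ± 0.916 to 2.84 ± 0.857 CPM, adjusted p = 1.2e-06). Cd5l, the G protein subunit gene Gna14 (−2.64), the transcription factor gene Msc (−2.61), Angptl7 (−2.48), Abcg3 (−2.39) and Malrd1 (−2.32) followed. The lower genes with the smallest p were Prss23 (−1.53, adjusted p = 7.6e-07), Col14a1, Prune2 (−1.72), Emcn and the protease-activated receptor gene F2rl1 (−1.84).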

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

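The tests of fewer stellate cells, of more or fewer macrophages and of the siRNA duplex, and the correction for GC content and length, were chosen only after the result was seen; the splits of the libraries were planned.

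In 14 of 358 groups of 4 values, a library lay far from the other 3 of its group, judged by its gap to the nearest value over the whole range of the group. Chance gives this in about 1 in 20 groups, or 17.9 of 358, so the number found is not above chance. In the siPAK4 group, replicate 1 was low for Col3a1 (87.6 CPM against 99.1 to 101, ratio 0.847) and replicate 4 was low for Ifit3 (118 CPM against 144 to 149, ratio 0.830) and Actg2 (0.238 CPM against 0.518 to 0.549, ratio 0.902) and high for Cnn1 (0.545 CPM against at most 0.399, ratio 0.884). The neutrophil marker level was also low in siPAK4 replicate 4 (−1.17 against −0.28 to −0.11, ratio 0.844). Replicate 3 of that group was low for Cald1 (190.03 CPM against 218 to 221, ratio 0.914) and for the level of CREB and immediate early genes (−0.17 against 0.04 to 0.05, ratio 0.945), and high for Cox6c (117 CPM against 96.3 to 98.5, ratio 0.893). In the siControl group, replicate 3 had the most counts (61535063 against 57297561 to 57833787, ratio 0.873), was high for Clec14a (27.9 CPM against 25.1 to 25.3, ratio 0.907) and Mki67 (359 CPM against 321 to 325, ratio 0.886) and low for Gusb (318 CPM against 337 to 339, ratio 0.890). Replicate 1 of that group was low for Sesn1 (40.5 CPM against 46.7 to 47.1, ratio 0.946), and replicate 2 was high for Myh11 (5.93 CPM against 4.17 to 4.34, ratio 0.903).

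Collagen and activation genes were lower with siPAK4. Fewer stellate cells in those cultures would lower quiescence genes alike, if stellate cells were their main source. The quiescence median lay 0.96 above the collagen median, more than the SD of 0.517 between quiescence genes. The source of these transcripts is not known, and the quiescence genes Lrat and Gfap had too few reads to test (at most 4 per siControl library). The comparison therefore does not decide whether there were fewer stellate cells. A GC or transcript length bias is argued against, since the collagen median was −0.72 after the correction. No biological explanation was tested, and neither was a change in the share of mesothelial cells, portal fibroblasts or vascular smooth muscle cells, whose marker lists were lower too. As all siPAK4 libraries received siRNA against PAK4, an effect of the siRNA itself cannot be told apart from Pak4 loss. That limit holds for every changed gene.

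Interferon response genes were higher with siPAK4. A larger share of macrophages would raise macrophage markers, but of 17 tested 0 were higher and 10 lower (median −0.66). This argues against it only as far as these markers follow cell number, and they did not move alike. A GC or length bias is argued against by an interferon median of 1.47 after the correction. Sensing of the targeting siRNA as foreign RNA cannot be told apart from an effect of Pak4 loss, since the median of 1.47 is what either could give and all siPAK4 libraries received siRNA against PAK4. The labels do not say whether 1 or several duplexes were used, and a rescue was not analysed here.

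The macrophage genes C1qb, Cd5l and Marco were lower with siPAK4. Fewer macrophages would lower all their markers by about the same factor, but the SD of the log2 fold changes of 15 markers (0.910) was 7.80 times their median standard error, and 6 of them did not pass the test. That standard error covers only the spread between libraries, which may be technical. No other list was measured in this way, so how often a list would show such a spread is not known. The markers did not fall alike. This argues against an equal loss of all macrophages as the whole cause only as far as macrophages alone made these markers, which was not tested. A loss of cells beside a change in the macrophages could remain. The list mixes Kupffer cell and general macrophage markers, so a loss of only some macrophages could also give unequal falls and was not tested.

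The splits argue against chance as the source of the count of changed genes. Only the real split, 1 of the 35 splits of the 8 libraries into 4 and 4, gave as many (4832, highest other 1). As 1 of 35 is the smallest share these splits can give, chance is not excluded. The same holds for genes changed at least 2-fold, with 1 of 35 splits (831, highest other 1). For the number of gene lists called by camera this count does not argue against chance, since 7 of 35 splits gave as many (17 in the real split, highest other 21). All 6 others exchanged 1 library of each group and so keep part of the real difference, and the 18 splits that exchanged 2 libraries of each group gave at most 11.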

How the results depend on the processing

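The correction for GC content and length was chosen after seeing the data; the other alternatives were chosen before. Pak4 was lower and past the threshold in every alternative (log2 fold change −1.56 to −1.04), and no gene called both by the chosen test and by an alternative changed its sign. As the alternatives refit the same libraries, a change of sign among such genes was unlikely from the start. The number of changed genes was 2634 at an adjusted p under 0.01, by construction of the stricter threshold, and 3543 to 5494 with a library left out, against 4832. Genes changed at least 2-fold numbered 831, against 503 with a mean of at least 1 CPM, where fewer low genes were tested, 309 with TPM and 220 with FPKM at a pseudocount of 1, 726 with TPM and 543 with FPKM at a pseudocount of 0.1 (these fits also changed the scaling and the test, and the cause was not tested), and 717 to 890 with a library left out. Camera called 17 lists, 16 to 18 with a library left out, 16 with the GC and length correction and 4 with an estimated correlation. That last repeat changed only the correlation between genes, from the preset 0.01 to the estimates. Among the 17 called lists these ran from 0.039 for vascular smooth muscle markers to 0.70 for interferon genes. A higher correlation makes camera more cautious, so p-values at the preset rest on a correlation below the estimated one. The replicate numbers gave no clear sign of pairing (correlations of −0.047 to 0.10, with 3 of 8 libraries correlating best with their own number). Such weak correlations do not show that the samples were unpaired. With the replicate as a block, 4587 genes, 813 genes at least 2-fold and 17 lists were called and Pak4 was at −1.46. Over all alternatives, 2975 values of single named genes stayed on the same side of the threshold with the same direction, 37 were no longer past it and 7 newly past it; for single lists these numbers were 654, 25 and 15.

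Direction turned only for 4 lists that camera did not call; the cause was not tested. Adjusted p-values for the turned CREB and immediate early genes were 0.978 with library totals, 0.943 with a mean of at least 1 CPM, 0.981 with TPM at a pseudocount of 1, 0.998 on ranks and 0.934 with the replicate block. For lysosome and autophagy genes they were 0.940 with limma-voom, 0.861 with no filter, 0.830 on ranks, 0.888 by fry and 0.972 with the replicate block, and for neutrophil markers 0.783 with no filter. With a library left out, the adjusted p ranged from 0.578 to 0.993 for CREB and immediate early genes, 0.392 to 0.971 for lysosome genes, 0.732 to 0.993 for neutrophil markers and 0.316 to 0.993 for oxidative phosphorylation genes, which turned without siControl replicate 1 (0.993) and siPAK4 replicate 3 (0.706). Genes such as Lrat and Pak7 had too few reads to test, although every library held at least 55728583 counts.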

Other observations

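The 5 gene groups here were written, and the genes named here chosen, after the main results were seen, with adjustment over these 5 groups. The MHC class I antigen presentation genes were higher with siPAK4, with 12 of 14 higher, 0 lower and 2 not past the test (13 higher when adjusted over the list alone; median 0.40, camera adjusted p = 4.5e-11, and adjusted p = 0.017 with an estimated correlation). The peptide transporter genes Tap1 (0.97) and Tap2 (0.53), the transactivator gene Nlrc5 (0.57) and H2-K1 (0.42) rose. Tap1 was already among the higher genes with the smallest p and was kept in the group, so the group's test partly reuses a gene already seen. Complement genes other than C1q went both ways, with 4 higher, 5 lower and 4 not past the test (6 and 5 when adjusted over the list alone; median −0.017, camera adjusted p = 0.63). Cfb rose (1.61) and the anaphylatoxin receptor gene C5ar1 fell (−1.20). The selectin genes Sele (from 7.17 ± 1.65 to 31.0 ± 6.15 CPM, adjusted p = 1.1e-05) and Selp (from 26.3 ± 5.62 to 114 ± 22.1 CPM, adjusted p = 8.7e-06) rose, while Vcam1, another leukocyte adhesion gene, fell (−0.56, adjusted p = 2.2e-05).

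Of 7 tested small leucine-rich proteoglycans 5 were lower, 0 higher and 2 did not pass (5 lower when adjusted over the list alone; median −1.03, camera adjusted p = 0.00016, and adjusted p = 0.032 with an estimated correlation). Bgn fell from 327 ± 43.2 to 118 ± 28.5 CPM (−1.47), Ogn (−2.46) and Lum (−1.03) fell, and Dcn was at 0.17 (adjusted p = 0.15). Of 15 basement membrane genes 8 were lower, 0 higher and 7 did not pass (8 lower when adjusted over the list alone; median −0.34, camera adjusted p = 0.00026; adjusted p = 0.11 with an estimated correlation), among them Lamc3 (−1.70), Lama2 (−1.19), Nid2 (−0.92) and the perlecan gene Hspg2 (−0.85).

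A hypothesis is that aryl hydrocarbon receptor activity may be higher with siPAK4, as Cyp1a1 and Aldh3a1 rose. Of 6 other targets 5 were tested, 3 were higher and 0 lower (median 0.46), with a camera p of 0.00028 before adjustment (adjusted p = 0.00035 over the 5 groups; adjusted p = 0.11 with an estimated correlation), so the support depends on that setting. Ahrr, the receptor's repressor and target, rose from 4.41 to 10.3 CPM (1.23, adjusted p = 3.1e-05; higher in 4 of 4 libraries) and Tiparp by 0.46, while Cyp1b1 was at 0.27 (adjusted p = 0.084). Nqo1, a target shared with NRF2, rose by 0.93. In the same libraries the hepatocyte markers had a median of 1.97, and whether a trace of hepatocyte RNA accounts for part of these rises was not tested.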
